A study of Mus musculus with 6 samples.

How the data were processed

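The series measured messenger RNA in skin of 6 male mice of a mixed C57Bl6/129Sv background, 3 wild-type (WT) and 3 with a conditional knockout of Sox4 in skin (KO), on 1-colour Agilent arrays. Skin was taken in telogen, the resting phase of the hair cycle, without treatment. Per the labels' protocols, total RNA was extracted with Trizol and purified on a column, RNA integrity numbers lay between 6.5 and 8.5, and the RNA was copied into Cy3-labelled RNA. Genotype, replicate number and age came from the labels. Within each group the 3 arrays carry 3 different ages, so they were treated as different animals.

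The scanner files hold spot intensity values that the authors deposited as Agilent Feature Extraction 11.5.1.1 wrote them, per the file headers, with no normalization between arrays. The processed signal in these files is background-subtracted and detrended by that program. Deposited flags of the other kind, coded 0 or 1, mark spots well above background, saturated spots and outliers, per the file headers. Each array held 62976 spots. The authors also deposited a value table on a log2 scale for the same 6 arrays; its column medians were 6.80 in each of 6 columns, and its processing steps are not given in the sources used here. The submitters' processing notes name limma, without a version or settings.

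Each column of the value table was set against the scanner values of all 6 arrays over 27353 probes, after removing each probe's mean. Every column headed with a WT sample followed the KO array of the same replicate number, and every column headed with a KO sample followed the WT array of that number, with correlations of 0.998 to 1. Correlations with the array named in the heading lay between −0.627 and −0.245. The values lay within a median of 0.0031 log2 of normexp background correction followed by quantile normalization computed here, so scale and centring were recovered from the values, while the group headings stand against the scanner files. The comparisons use the scanner files, whose samples are recorded per file, and the value table served as an alternative in both readings.

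The values tested were log2 of the processed signal minus each array's 75th percentile over non-control probes. Spots of a probe were averaged on the log2 scale without flagged outliers, and 31 of 55681 probes were left out because no unflagged spot remained on some array. The planned naming by a gene name column could not be used, since the scanner files carry accessions without one; accessions were matched without versions to a RefSeq table of assembly GRCm38.p6, which named 27497 probes and left 28153 without a symbol. Of the probes with a curated RefSeq transcript accession, 98.4% were named. The array grid refers to build mm9, so the table served for names and neighbour order, and no coordinates are given. Probes well above background on all arrays of at least 1 group were kept (30082 probes), and each gene was represented by its brightest kept probe, which gave 22823 genes and unnamed transcripts, 14919 of them with a symbol.

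Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided; fold changes are KO minus WT. A probe not well above background on any array of a group has a bound there. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. The genes named are Sox4, then up to 12 per direction among called genes without overlap between groups, by size. Open places were filled by smallest unadjusted p among genes with unadjusted p under 0.01, a log2 fold change of at least 1 in either direction and no overlap between groups; for each list described, the 2 to 4 members with the smallest p are named. Predicted genes and clone names were passed over.

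Before the data were examined, 35 gene lists of skin cell types, hair follicle, epidermal, metabolic and stress programmes were fixed, along with the tests and most alternatives. The 34 lists with at least 5 measured members were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. A list's score on an array is the median over members of the log2 signal minus the member's WT mean. The fit was tested on simulated data with the gene means and spreads of this comparison (22823 genes, 10 runs). In each run 200 genes were changed, by 1 or 3 log2 units. The fit recovered 91.5% of changes of 3 log2 units and 40.0% of changes of 1 log2 unit, with 4.36% false calls. The adjusted threshold loosens as more genes change, so these shares need not hold for the real comparison, which called 5. A list of 30 genes shifted by 0.5 log2 was called in 10 of 10 runs, and 0 of 300 unshifted lists were called; the simulated genes varied independently, so this says nothing about correlated members.

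The arrays lay on 3 slides. Slide 1 held WT replicate 1 and KO replicate 3, slide 2 held WT replicates 2 and 3 and KO replicate 1, and slide 3 held KO replicate 2. All were scanned on 1 day, slide by slide, so scan and slide are the same batch. Alternatives were normexp background correction (offset 50, on the median spot signal, since the files give no mean signal), quantile normalization, both together, the value table, 2 other filters on dim probes, all probes singly, trended and robust variance moderation, slide as fixed or random block, replicate number as block, age as covariate, array weights, 2 other thresholds, and each array left out.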

Results

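The data were 6 array profiles of untreated telogen skin from male mice, 3 WT and 3 with Sox4 conditionally deleted in skin. WT mice were 20, 19 and 18 weeks old and KO mice 17, 18 and 16 weeks old. Sox4 is a transcription factor of the SoxC group, and the series asked what it contributes to skin homeostasis in the resting phase. Between 52.1% (KO replicate 2) and 66.4% (KO replicate 1) of probes were well above background, and the 75th percentile of the processed signal ran from 379.8 in WT replicate 1 to 605 in KO replicate 1. No spot was saturated. The number of arrays limits the precision of every value below.

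Sox4 was lower in all 3 KO skins than in any WT skin. The brighter of its 2 probes read 503.7, 764.2 and 735.2 units in WT and 78.7, 69.0 and 59.5 units in KO, a log2 fold change of −3.56 (SE 0.13, n = 3 per group; limma adjusted p = 0.00135), or 11.8-fold lower. The difference was −3.46 on slide 1, −3.64 on slide 2 and −3.57 with slide as a block (adjusted p = 0.0442). The dimmer probe was not well above background on any KO array and lay at least 7.72-fold below WT. Exact two-sided permutation gave p = 0.1 for the brighter probe, the smallest that 3 against 3 arrays allow. Whether either probe lies in the deleted part is not given in the sources used here. A probe for the unnamed transcript ENSMUST00000067230, named here because the count of calls is small, fell by 3.54 on the log2 scale (SE 0.14, adjusted p = 0.00135). Its change was close to that of Sox4, and its gene is not given in the sources used here. It may therefore not be a call apart from Sox4. Slide as a block left Sox4 as the only call, so the call of this transcript was lost.

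Besides Sox4, 3 named genes passed the threshold. Aoah, an enzyme that inactivates bacterial lipopolysaccharide, fell by 2.57 on the log2 scale (SE 0.18, adjusted p = 0.0270), and Cd3g, a chain of the T cell receptor complex, fell by 1.32 (SE 0.11, adjusted p = 0.0464). Pitx1, a homeodomain factor of hindlimb identity, rose by 2.89 (SE 0.23, adjusted p = 0.0464), from a WT mean of −2.79 ± 0.39 to 0.10 ± 0.24 in KO (SD, n = 3, relative to the 75th percentile). On slides 1 and 2, Aoah differed by −2.83 and −2.31, Cd3g by −1.19 and −1.38, and Pitx1 by 2.37 and 2.92. With slide as a block the values were −2.53 for Aoah (adjusted p = 0.165), −1.30 for Cd3g (adjusted p = 0.322) and 2.68 for Pitx1 (adjusted p = 0.165), so these 3 calls were lost while Sox4 stayed called. Leaving out WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 2 also ended each of them, with adjusted p up to 0.211, 0.295 and 0.211 for Aoah, Cd3g and Pitx1; over all 6 leave-one-out fits the values stayed within −2.68 to −2.40, −1.38 to −1.29 and 2.69 to 3.09.

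**Figure D1:**
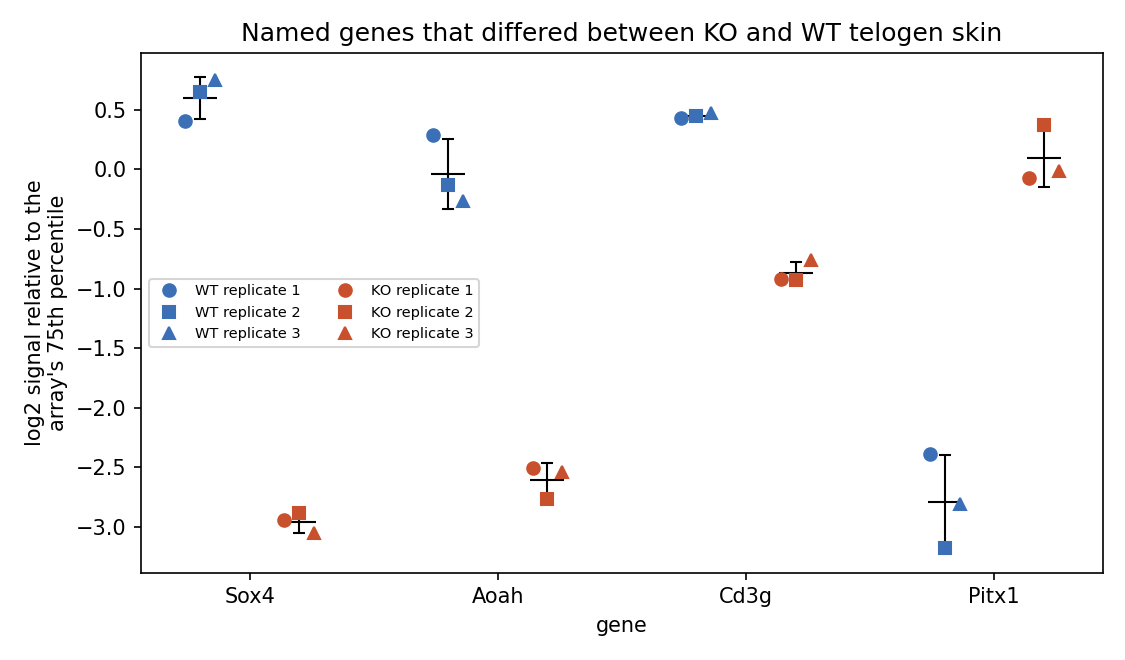
Each point is one array's log2 signal relative to the array's 75th percentile (vertical axis) for the 4 named genes that passed the threshold (horizontal axis), blue for WT and orange for KO, with bars for the mean and SD of 3 arrays. The 3 KO points of Sox4, Aoah and Cd3g lie below all WT points, and those of Pitx1 lie above.

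In all, 5 of 22823 genes and transcripts passed the threshold, 1 higher and 4 lower in KO, the unnamed transcript among the 4. Unadjusted p was under 0.05 for 2685 (1429 higher, 1256 lower), where chance alone gives about 1141, and KO and WT values did not overlap for 4413 (19.3%, chance 10%). The median log2 fold change of all genes was −0.09. The count rested on single arrays: it was 303 without WT replicate 1, 88 without KO replicate 3, 3 without KO replicate 1, and 2 without WT replicate 2, WT replicate 3 or KO replicate 2. With age as a covariate, which differed between groups, it was 141 (131 higher), and with slide as a block it was 1.

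The other genes named by rule missed the adjusted threshold, with adjusted p from 0.0505 to 0.208. Among those lower in KO, Lrp2, the endocytic receptor megalin, was not well above background in KO and lay at least 4.91-fold below WT. Sugct, a mitochondrial transferase, lay at least 2.06-fold below WT by the same bound. The natural killer cell receptors Klrd1, Klrb1b and Kir3dl1 had log2 fold changes of −1.34 (SE 0.14), −1.38 (SE 0.15) and −2.27 (SE 0.23), Kir3dl1 being well above background on 1 KO array. The cholesterol synthesis enzyme Hsd17b7 had −1.19, the stress cytokine Gdf15 −1.61 and the gasdermin Gsdma2 −1.18. Higher in KO were Aqp4, a water channel (4.46-fold), Ppp1r27 (4.42-fold), the glutamate receptor subunit Grin3b (2.83-fold), Lrtm1 (2.69-fold) and the paraoxonase Pon1 (2.64-fold). The phosphatase Dusp26 was 2.44-fold, the carbonic anhydrase Car14 2.15-fold and dysferlin, Dysf, a protein of muscle membrane repair, 2.14-fold higher. Among WT arrays, Aqp4 and Ppp1r27 lay nearest to KO in replicate 1 (−1.20 and 1.46), as did the skeletal muscle score described below. The same held for the called gene Pitx1 (−2.39) and for Lrtm1, Pon1, Dysf, Car14 and Tafa3. Grin3b, Sec31b, Cyp2j11 and Dusp26 lay nearest to KO in WT replicate 3, and Dusp26 was lowest in WT replicate 1 (0.17). Tafa3, Sec31b and Cyp2j11 were not well above background in WT and lay at least 2.81, 1.61 and 1.35-fold higher in KO.

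**Figure D2:**
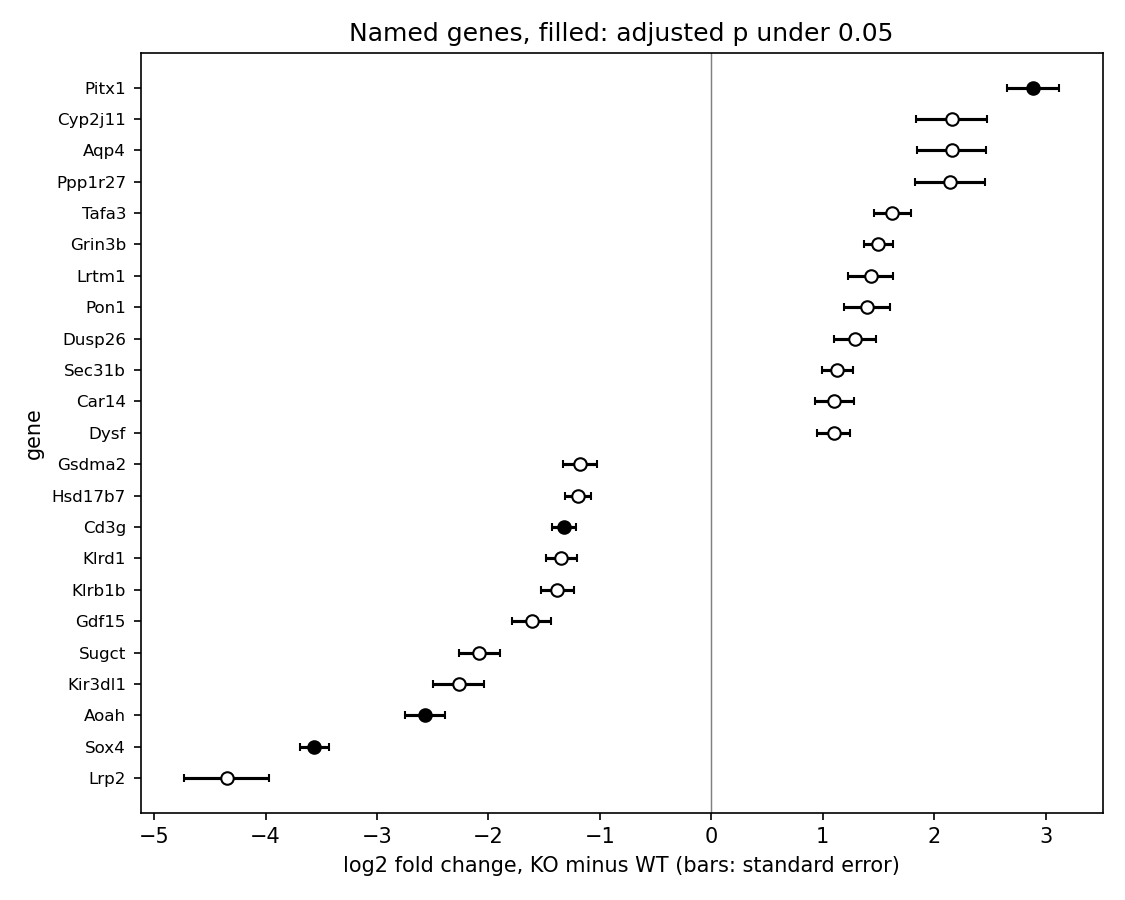
Log2 fold change, KO minus WT (horizontal axis), of 23 of the 24 genes taken by the rule (vertical axis) with its standard error; filled points passed an adjusted p of 0.05 and open points did not. Values run from −4.35 for Lrp2 to 2.89 for Pitx1; for genes not well above background in one group the point is the fitted value, not the bound.

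T cell and natural killer cell genes were lower in KO skin. All 24 measured members of the list had negative fold changes, with a median of −0.77 on the log2 scale, and 20 had no overlap between groups. When adjusted over the list alone, 18 fell; 1, Cd3g, passed over all genes. Cd3e (−1.16, SE 0.15) and Zap70 (−1.097, SE 0.15), parts of T cell receptor signalling, were among the 18. The list's scores were −0.81, −0.85 and −0.66 in KO replicates 1, 2 and 3 and −0.12, −0.05 and 0.13 in the WT replicates. Camera called the list (adjusted p = 1.6e-16) and so did fry (adjusted p = 0.0228), while adjusted p = 0.48 with an estimated correlation. The shift was −0.57 on slide 1, −0.84 on slide 2 and −0.72 with slide as a block. With the skeletal muscle score as a covariate, chosen after seeing the data, it was −0.53 (camera adjusted p = 2.45e-13).

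Camera with the preset correlation called 15 of 34 lists, 8 higher and 7 lower in KO. With an estimated correlation it called none of the 34 (smallest adjusted p = 0.48), and fry called the T and NK cell list alone. The values of the other 14 lists therefore describe these 6 arrays only. Camera sets a list against the other genes, but the medians given are the fold changes themselves. Of all 22823 genes and transcripts, 14629 were lower in KO (median −0.09), which bears on every count of negative members.

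Cholesterol synthesis and sebaceous gland genes lay lower in KO. Of 25 cholesterol synthesis genes, 24 had negative fold changes (median −0.41, camera adjusted p = 3.22e-05), and 3 fell when adjusted over the list alone. The 3 were Hsd17b7, Msmo1 (−0.72, SE 0.17) and Lss (−0.83, SE 0.20), all enzymes of the pathway. Of 22 sebaceous gland genes, 19 were negative (median −0.31, camera adjusted p = 0.000817), and 5 fell over the list alone, among them Hsd3b6 (−0.99), Elovl3 (−0.76), Fa2h (−0.80) and Acsm3 (−0.63). For both lists adjusted p = 0.765 with an estimated correlation. On slide 1 the cholesterol shift was −0.05 and on slide 2 −0.41 (−0.27 with the block); the sebaceous shifts were −0.05, −0.25 and −0.13 in the same order. Without WT replicate 2 the cholesterol median was −0.20 and without KO replicate 2 the sebaceous median was −0.15; with the muscle score as a covariate the medians were −0.02 and 0.02 and both calls were lost (adjusted p = 0.778 and 0.643).

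Skeletal muscle genes were higher in KO. All 34 measured members had positive fold changes (median 1.81, 3.51-fold), and 31 rose when adjusted over the list alone, such as Ckmt2 (2.22, SE 0.51), Atp2a1 (2.17, SE 0.53), Pygm (2.04, SE 0.52) and Des (1.55, SE 0.40), which act in muscle energy supply, calcium uptake and the cytoskeleton. None passed over all genes. Camera gave adjusted p = 2.7e-26, against adjusted p = 0.645 with an estimated correlation and 0.247 by fry. The scores were 1.74, 2.19 and 1.54 in KO and 1.20, −0.50 and −0.70 in WT, so WT replicate 1 lay close to the KO arrays. The shift was 0.35 on slide 1, 2.36 on slide 2 and 1.49 with the block.

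Mitochondrial electron transport genes lay higher in KO. Of 66 measured, 62 had positive fold changes (median 0.28, camera adjusted p = 2.39e-18, adjusted p = 0.671 with an estimated correlation), and none passed over the list alone; Cycs (0.72), Atp5g1 (0.65), Ndufc1 (0.48) and Uqcrc1 (0.51) had the smallest p. The slides gave 0.20 and 0.13, and the block 0.18; the median was 0.18 without KO replicate 2 and 0.16 with the muscle score as a covariate, both called. The brown adipocyte list (median 0.71, camera adjusted p = 0.00983, adjusted p = 0.48 with an estimated correlation) had 5 of 9 members higher over the list alone. These included Cox8b (1.67), Cox7a1 (2.01) and Cpt1b (1.80), which are also expressed in muscle. The slide values of the list were 0.47 and 0.53, with 0.50 under the block. With the muscle score as a covariate its median was 0.12 (camera adjusted p = 0.367).

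Hair shaft and inner root sheath genes were high in KO replicates 1 and 2 and at the WT level in KO replicate 3. The scores were 4.01, 3.53 and −0.14 in KO and −0.11, 0.23 and −0.10 in WT. The median over 29 members was 2.61 (26 positive; camera adjusted p = 5.91e-11, adjusted p = 0.671 with an estimated correlation), and none passed over the list alone. The hair keratin Krt86 read −2.28, −2.63 and −2.15 in WT and 4.26, 3.22 and −1.51 in KO, and the follicle enzyme Padi3, well above background on 1 WT array, read −4.64, −4.68 and −4.02 against 1.67, 0.87 and −3.96. Crym and Krt84 had log2 fold changes of 2.86 (SE 0.88) and 1.42 (SE 0.52). The shift was 0.09 on slide 1, 4.0 on slide 2 and 2.34 with the block. Without KO replicates 1 and 2, a setting chosen after seeing the data, it was −0.14 (camera adjusted p = 0.528), and without KO replicate 3 it was 3.93.

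**Figure D3:**
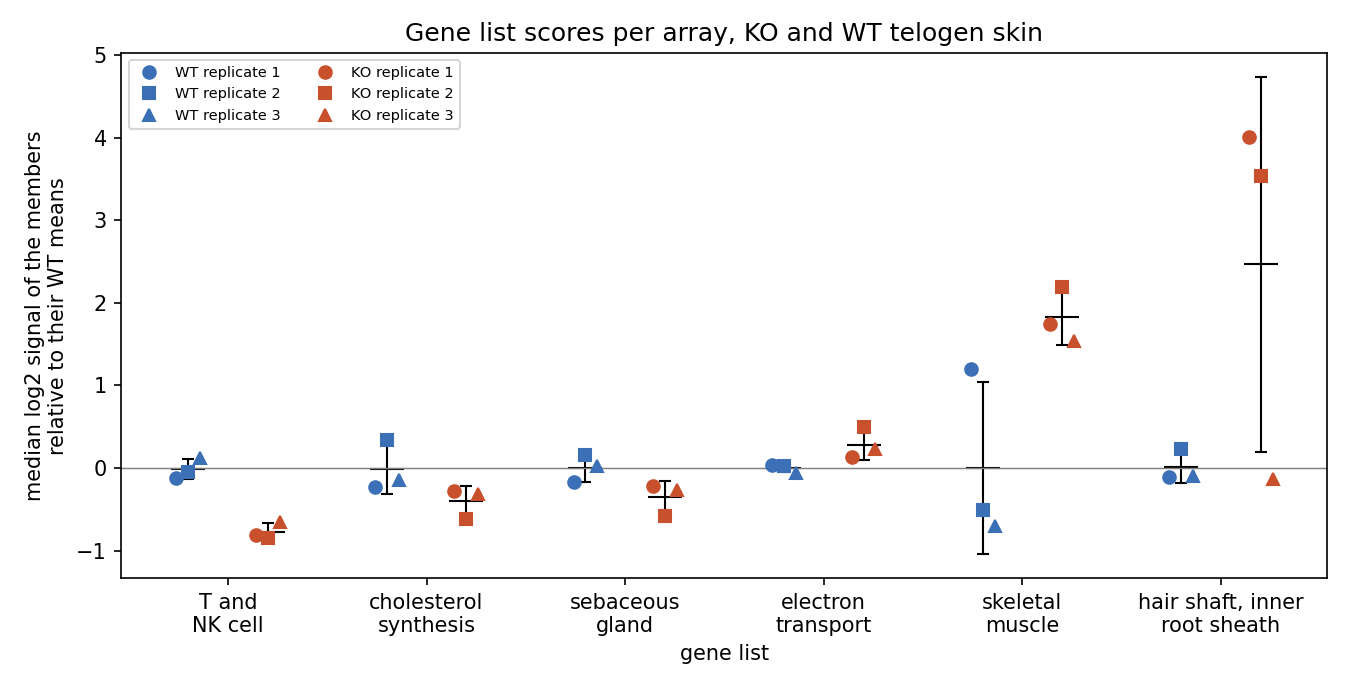
Score of each array (vertical axis, the median over a list's members of log2 signal relative to the member's WT mean) for 6 gene lists (horizontal axis), blue for WT and orange for KO, with bars for the mean and SD of 3 arrays. T and NK cell scores of the KO arrays lie between −0.85 and −0.66, below all WT arrays, while the hair shaft score of KO replicate 3 lies at the WT level.

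Among the remaining lists called with the preset correlation, the peripheral nerve list had a median of 0.13 (adjusted p = 0.000467), and the myelin genes Prx (0.88, SE 0.11) and Mal (0.55, SE 0.12) were among those that rose when adjusted over the list alone. All 72 cytosolic ribosome genes had negative fold changes with a median of −0.19 (adjusted p = 6.78e-08), of which Rps21 (−0.47) had the smallest p, and none passed over the list alone. Terminal differentiation genes had a median of −0.24 (camera adjusted p = 0.00276, Elovl4 −0.66, Lce1m −0.37). Macrophage and dendritic cell genes had −0.21 (camera adjusted p = 0.0124, Ms4a7 −0.67, but Cd163 0.83). B cell genes had −0.66 (camera adjusted p = 0.0363), with 5 of 6 members negative. Among them Jchain (−4.31, SE 1.46) was well above background on 1 KO array and overlapped between groups. Cd79b (−0.78) and Cr2 (−0.54) did not overlap. Red blood cell genes had 0.52 (adjusted p = 0.0124), positional Hox genes 0.06 (adjusted p = 0.0209; Hoxc6 0.46, Hoxc5 0.63) and mast cell genes 0.22 (adjusted p = 0.0363; Hdc 0.96). With an estimated correlation adjusted p was 0.48 for nerve, 0.765 for ribosome, 0.671 for B cell, red blood cell and Hox, and 0.816 for terminal differentiation, macrophage and mast cell. Slide 1 and slide 2 gave 0.24 and 0.21 for nerve, −0.07 and −0.33 for ribosome, −0.03 and −0.31 for terminal differentiation, −0.05 and −0.39 for macrophage, and −0.33 and −0.66 for B cell genes. They gave −0.16 and 0.44 for red blood cell, 0.15 and −0.03 for Hox, and 0.01 and 0.24 for mast cell genes. With slide as a block the shifts were 0.17, −0.22, −0.18 and −0.23 for nerve, ribosome, terminal differentiation and macrophage genes; the calls of B cell (−0.33, adjusted p = 0.0747), red blood cell (0.27, adjusted p = 0.0578), Hox (0.02, adjusted p = 0.0578) and mast cell genes (0.12, adjusted p = 0.138) were lost. Single arrays also ended calls: terminal differentiation without WT replicate 2 (−0.12) or KO replicate 3 (−0.23), macrophage without WT replicate 3 (−0.13), red blood cell without WT replicate 2 (0.30), and B cell without WT replicate 1 (−0.71), WT replicate 3 (−0.51) or KO replicate 3 (−0.77). Hox genes lost theirs without WT replicate 3 (0.09), KO replicate 2 (0.04) or KO replicate 3 (0.04), and mast cell genes without WT replicate 1 (0.13), WT replicate 2 (0.006), KO replicate 1 (0.19) or KO replicate 2 (0.10). With the muscle score as a covariate, nerve (0.22) and ribosome genes (−0.07) kept their calls. Those of mast cell (0.29), Hox (0.07), B cell (−0.36), macrophage (−0.09), terminal differentiation (0.03) and red blood cell genes (−0.36) were lost, the last 2 with the sign turned. With 1 array left out the nerve median ran from 0.09 to 0.24, called each time. Over the same fits terminal differentiation ran from −0.39 to −0.12, macrophage from −0.32 to −0.13, B cell from −0.77 to −0.39, red blood cell from 0.30 to 0.81, Hox from 0.01 to 0.14 and mast cell genes from 0.006 to 0.50.

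The other 19 lists did not pass the list test. Median log2 shifts were −0.13 for hair follicle stem cell genes, −0.02 for the Wnt pathway, −0.06 for the BMP and TGF-beta pathway, −0.13 for the Notch pathway, −0.12 for dermal papilla, −0.15 for basal epidermis and −0.11 for epidermal stress genes. They were 0.05 for cell cycle genes, −0.10 for p53 targets and cell cycle inhibitors, −0.15 for the unfolded protein response, 0.11 for immediate early genes, 0.01 for the interferon response and −0.00318 for circadian clock genes. Dermal collagen and fibroblast (−0.14), white adipocyte (−0.24), smooth muscle (−0.05), endothelium (−0.01), melanocyte pigment (−0.11) and neutrophil genes (0.18) did not pass either. Adjusted p over these 19 lists ran from 0.106 to 0.932, and camera pointed up where the median was negative for Wnt, dermal papilla, smooth muscle, endothelium, melanocyte and circadian genes. The mean was negative where the median was positive for interferon and neutrophil genes. With slide as a block, cell cycle (0.13, adjusted p = 2.24e-05) and smooth muscle genes (0.15, adjusted p = 0.0167) were called higher. With 1 array left out, cell cycle genes were called in 4 of 6 fits and ran from −0.07 to 0.17, and smooth muscle genes were called in 2 and ran from −0.21 to 0.22. White adipocyte (−0.58), epidermal stress (−0.47), collagen (−0.17), circadian (0.13), interferon (0.13) and immediate early genes (0.25) were called in 1 fit each, at these values. With the muscle score as a covariate, 5 of the 19 were called: cell cycle (0.38, adjusted p = 3.42e-07), smooth muscle (0.68, adjusted p = 2.03e-07), white adipocyte (0.60, adjusted p = 2.45e-13) and epidermal stress genes (0.46, adjusted p = 0.00547) higher, and collagen genes (−0.16, adjusted p = 0.0203) lower. Smooth muscle, white adipocyte and epidermal stress genes thereby turned sign.

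Across all tested genes, array pairs within WT correlated at 0.984 to 0.989, within KO at 0.978 to 0.985 and between groups at 0.963 to 0.991. The closest pair was WT replicate 1 with KO replicate 3, which shared slide 1. The first principal component held 50.5% of the variance, with WT replicates at 13.1, 46.3 and 42.1 and KO replicates at −30.5, −71.0 and 0.02.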

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

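The tests of hair shaft, muscle and chromosome 13 genes in this part were chosen after the results were seen; the splits of the arrays were planned. In the authors' value table, which the comparisons of the report do not use, the Sox4 probe was 2.56 log2 higher in the columns headed KO than in those headed WT. Its values were 6.84, 7.03 and 6.84 in the columns headed WT and 9.33, 9.54 and 9.52 in those headed KO, the opposite of the scanner files. This signal was singled out because it lies in data outside the main measurement. Each column carried the values of the array with the same replicate number in the other group, so every direction read from the table as headed is turned.

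The 6 arrays split in 10 ways into groups of 3. The real split called 5 genes, the highest of the other splits called 0, and 1 of the 10 splits called as many as the real one. For lists, the real split called 15 and the highest of the others 16, and 4 of the 10 splits called at least 15. With 10 splits no share under 0.05 can be reached. List calls with the preset correlation were thus as many under groupings that mix the genotypes, such as WT replicates 1 and 2 with KO replicate 2, which called 16.

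Hair shaft and inner root sheath genes stood 4.01 and 3.53 log2 above WT in KO replicates 1 and 2 and at −0.14 in KO replicate 3. For KO replicate 1, slide as the whole cause is argued against by slide 2, where it exceeded WT by 4 log2, over 3 SDs of the WT scores. KO replicate 2 (3.53) was alone on slide 3, so for it slide cannot be told apart, and a part of Sox4 loss in the pattern was not tested. Growing follicles in these 2 samples may account for the pattern but stay open. Of 3 gene sets outside the list, 1 exceeded all WT arrays in both, melanin synthesis genes with 1.26 and 1.46 (highest WT 0.26). Other follicle genes had 0.95 and 0.21 (highest WT 0.33), and cell cycle genes 0.33 and −0.03 (highest WT 0.16). Of the 11 other follicle genes, 5 lay above all WT arrays in both: Krtap17-1, Krtap5-2, Prr9, Tchhl1 and Dlx2. In KO replicate 3 each of the 5 lay within the WT range. That set's score is a median, so 5 raised members of 11 need not lift it, and it cannot decide. The planned melanocyte list, which adds Mitf and Rab38 to the 5 measured melanin genes, had 0.164 and −0.102 (highest WT 0.166). The melanin result thus did not hold on it.

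Skeletal muscle genes were 1.81 log2 higher in KO by the median. The 2 cell types read for this, endothelium and white adipocyte, did not rise alike with muscle over all arrays. Brown adipocyte (0.71) and red blood cell genes (0.52) were higher, by less than muscle. On slide 1 smooth muscle (0.656) and brown adipocyte genes (0.465) rose by more than muscle, while endothelium (0.03) and red blood cell genes (−0.16) did not. Endothelial genes were at −0.01 (−0.0464 to 0.057 with 1 array left out) and white adipocyte genes at −0.242 (−0.578 to −0.0216). A lower share of epidermis and dermis stays open, since endothelium lies in the dermis too and its value cannot decide this. Terminal differentiation (42 of 46), basal epidermis (12 of 13) and collagen genes (31 of 40) were mostly negative, as were 14629 of all 22823 genes and transcripts. The white adipocyte value is less firm than the endothelial one. It was 0.374 on slide 1, where muscle rose by 0.351, and 0.60 with the muscle score as a covariate. Slide stays open: the shift was 2.36 on slide 2, where the 2 WT arrays differed by 0.23, but 0.351 on slide 1, and with slide as a block the list score differed by 1.48 (SE 0.71, under 3 SEs), while camera with that block called the list (median 1.49). A different amount of muscle tissue in the skin pieces is a candidate explanation, since within groups members followed the score of the other members with a median correlation of 0.968 (33 of 34 over 0.5), which cannot separate muscle taken along at dissection from a change with genotype.

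Sox4, Aoah, Pitx1 and Sugct all lie on chromosome 13. A segment inherited with the targeted allele in this mixed background, or an effect of the locus on its neighbours, might mark genes close to Sox4. Of the 100 measured genes nearest to Sox4, 1 (Ly86) had p under 0.001, against 60 of 14818 others, an odds ratio of 2.48 (95% interval 0.0613 to 14.7, Fisher's exact p = 0.337). Over the chromosome, 6 of 552 genes had p under 0.001, among them the 3 that prompted the count, Aoah, Sugct and Pitx1, which lie 62, 75 and 158 measured genes from Sox4. The interval is too wide to decide, and strain differences within this background were not tested.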

How the results depend on the processing

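Settings without KO replicates 1 and 2, with the muscle score as a covariate, and with value table columns matched to arrays were chosen after seeing the data. The count of 5 genes was 8 with normexp, 11 with quantile normalization, 8 with both, 8 in the matched value table, 9 with probes above background on all 6 arrays, 8 with trended and robust moderation, 15 with slide as a random block, 17 at adjusted p under 0.1, 141 with age and 662 with array weights, and all 5 genes stayed called in those. It was 2 without a filter, 3 with probes tested singly, 1 with slide as a fixed block and 2 to 303 with 1 array left out. Without KO replicates 1 and 2 and with the muscle covariate limma called 0 genes (1019 and 694 at unadjusted p under 0.05), and Sox4 was −3.66 (adjusted p = 0.145) and −3.33 (adjusted p = 0.195). Over 21 settings, leaving aside the value table as headed, Sox4 ran from −3.67 to −2.55 with adjusted p from 0.000168 to 0.195. The fits without KO replicates 1 and 2 and with the muscle covariate leave fewer residual degrees of freedom. The age covariate leaves as many as the muscle covariate and called 141 genes, so this alone does not account for the muscle fit. The cause of the moves was not tested.

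Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.128, −0.0363 and 0.0808. With the replicate block limma called 0 genes (2217 at unadjusted p under 0.05), and Sox4 stood at −3.56 (adjusted p = 0.103). Scan could not be fitted apart from slide.

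Taken as headed, the value table turned every direction by construction: 8 genes (7 higher, 1 lower), Sox4 2.56, Pitx1 −2.13, Aoah 1.85, Cd3g 1.15, Lrp2 1.11 and Hsd17b7 1.12. List medians were −1.81 for skeletal muscle, −0.30 for electron transport, 0.58 for T and NK cell, −2.39 for hair shaft, 0.10 for ribosome, 0.35 for cholesterol synthesis, −0.10 for Schwann cell, 0.26 for sebaceous gland, 0.19 for terminal differentiation, −0.64 for brown adipocyte, 0.20 for macrophage, −0.44 for red blood cell, −0.0911 for Hox and 0.32 for B cell genes. In the other settings 0 named genes changed sign.

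The 15 called lists became 0 with an estimated correlation and 1 with fry. The T and NK cell list stayed between −0.98 and −0.53 and was called in 22 of 23 settings. With the muscle covariate the cholesterol, sebaceous and terminal differentiation medians were −0.02, 0.02 and 0.03, no longer called. Probes near background limit Lrp2, Sugct, Tafa3, Sec31b and Cyp2j11 to bounds.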

Other observations

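Within the p53 and white adipocyte lists, which did not pass, the members with the smallest p went both ways. Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 regulator p19, read 1.83, −1.62 and 1.002 in WT and −2.88, −1.59 and −2.80 in KO, a log2 fold change of −2.83 (SE 0.89, limma adjusted p = 0.334) with overlap at WT replicate 2. In the same list Ccng1 and Ddit4l had 0.84 (SE 0.26) and 1.45 (SE 0.44), and Pmaip1 −0.55 (SE 0.17). Among adipocyte genes, Car3 (0.77, SE 0.14) and Slc2a4 (1.43, SE 0.31), both also expressed in muscle, were higher in KO over the list alone, while Tmem45b had −1.05 (SE 0.25). With higher p, Mest (−2.25, SE 1.03) and Lep (−1.78, SE 0.60) were lower and Adrb3 (1.21, SE 0.51) was higher in KO, each without overlap between groups.

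Of 7 melanocyte genes, Tyrp1, Dct and Pmel lay above all WT arrays in KO replicates 1 and 2, and the other 4 had negative fold changes. The list's scores did not divide the arrays, at 0.164, −0.102 and −0.0484 in KO and 0.103, 0.166 and −0.281 in WT. Tyrp1 read −0.76, −0.95 and −1.63 in WT and 0.84, 1.04 and −0.61 in KO, and Dct 2.15, 1.85 and 1.40 against 3.06, 3.26 and 2.05. Tyr had −0.11 and Mlana −0.46 (SE 0.25). The Wnt effector Lef1, which also stands in the hair shaft list, read −0.79, −1.06 and −2.35 in KO replicates 1, 2 and 3 against −1.88, −2.11 and −2.52 in WT. In the unfolded protein list, Chac1 read 3.02, 4.31 and 1.96 in KO and 1.37, 1.55 and 1.11 in WT (log2 fold change 1.75, SE 0.55, adjusted p = 0.336).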
